A study of Laodelphax striatellus with 6 samples.

How the data were processed

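Small RNAs of the midgut were sequenced from 6 libraries of the small brown planthopper, 3 labelled as infected with rice black-streaked dwarf virus (RBSDV) and 3 labelled as RBSDV-free. Per the labels' protocols, about 5 µg of Trizol-extracted total RNA entered each library, the libraries were made with a TruSeq small RNA kit, and they were read on a HiSeq 2500. Read trimming, mapping, the miRNA database, the genome build and the counting tool are not given in the sources used here. Groups came from the treatment label and replicate numbers from the library titles. The labels do not say whether the libraries came from separate pools of insects, so the p-values measure the spread between these 6 libraries, which may be partly technical.

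The authors deposited a single table with 904 rows and 799 distinct names, in which each row is a small RNA sequence with a name, a length of 18 to 26 nt, a raw value and a scaled value per library. The authors deposited the raw values without normalization, per the file headers. They were treated here as estimated counts, since 253 rows as deposited hold a value that is not whole in at least 1 library, as when the reads of a sequence are divided over its rows. Summed over the rows of a name, the counts were whole within 0.05 in all 6 libraries for 726 names and not for 73. The values were rounded to whole numbers before the count tests. The smallest nonzero raw value was 2.5, so a listed 0 can stand for a few reads, and no upper limit was computed for a row at 0. The scaled values that the authors deposited are a signal equal to the raw value times 1 factor per library, from 0.767 for RBSDV-infected replicate 3 to 1.26 for RBSDV-infected replicate 2. How those factors were made is not given in the sources used here, and they served only as an alternative scaling. The table held 0 columns of other samples.

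Of the rows, 192 carry the name of a database miRNA (166 distinct names), with a 3-letter prefix for the species of the entry, and 712 carry a PC name and are called predicted candidates here. Suffixes such as R+2, L-1 or 1ss22CA follow many names. Their meaning is not given in the sources used here, and they were read as nucleotides gained or lost at the left and right end and as substitutions. Removing the L and R shifts from the row lengths gave a single reference length for 30 of the 31 reference names with 2 or more rows. The sequences themselves, a genome and an annotation were not used here, so no coordinates are given, and whether an added nucleotide matches the genome was not analysed here. Some rows under different names have identical counts, and rows of related miRNAs can share reads, so single members of a family are uncertain.

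Differences were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with the group, quasi-likelihood fit with robust dispersion, two-sided, infected minus virus-free), with Benjamini-Hochberg adjustment over the tested rows and a threshold of 0.05. The filter left 352 rows with 309 distinct names, 140 annotated and 212 candidates. The rows left out held 0.0528% of the counts. Total counts per library ran from 1903738 to 3277015, and these depths limit mostly the rare rows. Abundances are CPM, counts scaled to a common library total with the TMM factors, and standard errors of log2 fold changes come from the quasi-likelihood F statistic. A total of 17 lists of miRNAs by family, cluster, function or tissue was fixed beforehand, and a row joined a list by the number in its name. Lists with at least 3 tested rows were tested with camera at the preset correlation of 0.01, with an estimated correlation and with fry. Arm ratios were tested with limma 3.58.1 on log2((5p count + 0.5)/(3p count + 0.5)) for rows with the same species prefix and miRNA name, where both arms had a mean of at least 10 counts. Shares of counts were compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

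Some steps were chosen after the data were seen. Rows at least 1 nt longer than the most abundant row of the same miRNA number and arm were set against that row, by the log2 ratio of their counts (pseudocount 0.5) in limma. Letters in miRNA names were ignored there, so a few pairs join paralogs, and a name without an arm took the arm of the most abundant row of its number. Annotated rows were also summed per miRNA number and arm. The shares of counts in midgut marker rows and in rows of 24 to 26 nt were added to the composition measures, as were the authors' scaling, the summing of rows of a name and the removal of each library's straight-line trend on sequence length to the alternatives.

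The rule for naming rows, also fixed beforehand, took (a) up to 10 annotated rows past the threshold in each direction, by size of change, with a mean of at least 10 CPM and no overlap between the groups, (b) up to 3 predicted candidates in each direction by the same rule, (c) the 10 most abundant rows, (d) up to 3 of the most abundant tested rows of each list, (e) where nothing passed in a direction, the 5 rows with the smallest p there, and (f) up to 3 arm ratios past the threshold in each direction. Rows named outside this rule are said to be so.

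The fits were tested on simulated data. With 200 of 904 rows changed, infected against virus-free, 363 rows passed the filter. Of the changed rows tested, 7 of 29 were recovered at 2-fold (24.1%), 27 of 36 at 4-fold (75%) and 33 of 35 at 8-fold (94.3%), with 4 false calls among 263 unchanged rows. Recovery with a smaller share of changed rows, which the adjustment treats more strictly, was not simulated and may be lower. All rows were drawn with 1 common dispersion of 0.218, so these shares do not hold for rows with another spread, such as the abundant ones. The arm ratio fit called 0 of 15 unchanged pairs and the 1 pair changed by 16-fold, and camera called 3 of 14 lists when the midgut list was raised 4-fold: that list, and the growth and metabolism miRNAs and the Toll or Imd regulators, which each share 1 miRNA number with it. With a false straight-line trend on length added, 25 of 348 rows passed without the length correction, and with it only the 1 row that had also been raised 16-fold. The added trend had the form that the correction removes and 1 slope for all infected libraries. It therefore cannot show how the correction does with other trends.

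The alternatives fixed before the data were examined, as were the lists and the tests named with them, were other scalings (DESeq2-type size factors, library totals, upper quartile), no filter and a filter of at least 10 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, no robust dispersion, a replicate block, identical rows kept once, annotated rows only, the 3 most abundant rows left out and each library left out in turn. For arm ratios they were a pseudocount of 1 and a mean of at least 50 counts, and for lists the estimated correlation. Figures were drawn with matplotlib 3.10.9.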

Results

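Rice black-streaked dwarf virus (RBSDV) is a double-stranded RNA virus of rice and other cereals that the small brown planthopper, Laodelphax striatellus, takes up with plant sap and passes on after the virus has multiplied in its body. The midgut is the tissue that ingested virus meets first. Small RNA libraries of midguts from RBSDV-infected and RBSDV-free insects, 3 of each, were compared to find which miRNAs differ in abundance. Total counts were 2666181, 2732129 and 2779027 in virus-free replicates 1, 2 and 3 and 1903738, 1922402 and 3277015 in the infected ones. The table resolved miRNAs into sequence variants, so a miRNA could appear as several rows of different length. Libraries of a group were not near copies of each other: the chi-square per degree of freedom between their counts was 66.6 for infected replicates 1 and 2 and 215 to 238 for the virus-free pairs, all below the pairs across the groups (265 to 505). Infected replicate 3 stood apart from its group, at 366 and 401 from infected replicates 1 and 2. This measure grows with depth, and infected replicates 1 and 2 had the fewest counts. The correlation of log2 CPM did not part the groups. It was 0.955 to 0.966 for the virus-free pairs, 0.937 to 0.970 for the infected pairs and 0.936 to 0.966 across the groups.

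The midgut profile was led by a few insect miRNAs in both groups. The most abundant row was isc-miR-750, with 16.01% ± 3.03 of counts in virus-free and 15.5% ± 0.443 in infected libraries (SD, n = 3). It was followed by dme-miR-14-3p, of a miRNA that acts in fat metabolism and cell survival in Drosophila, at 10.5% ± 1.16 and 9.38% ± 0.361. The variant dme-miR-8-3p, of a miRNA that acts in growth and insulin signalling, held 9.80% ± 1.43 and 9.96% ± 3.06. The variant dme-miR-276b-3p_2ss10AC21CT held 8.56% ± 0.235 and 7.13% ± 0.594. The rest of the 10 most abundant rows were the candidates PC-3p-12_317818 and PC-3p-16_259636, bmo-miR-279c-3p_1ss12AT, ame-miR-1175_1ss17AT, dme-miR-281-3p_R-1_2ss10AG22GA and bmo-miR-13a-3p_R+1_2ss20TA21GA, each with a mean of 2.49% to 3.73% of counts. None of these 10 rows passed the threshold, and their log2 fold changes lay between −0.72 for the miR-1175 row and 0.36 for PC-3p-12_317818.

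In infected midguts 9 of the 352 tested rows were higher and 0 were lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 7 were variants of known miRNAs: miR-8, miR-750, miR-965, miR-2, miR-275, miR-14 and miR-184. They rose by 2.75-fold to 8.60-fold on the fitted scale. The other 2 were abundant predicted candidates. The largest change was that of aae-miR-8-5p_R+2, from 15.98 ± 4.88 to 138 ± 59.4 CPM (mean ± SD, n = 3 each), a log2 fold change of 3.10 ± 0.48 (SE, adjusted p = 0.0114).

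The variant isc-miR-750_R+1_1ss22CA rose from 561 ± 104 to 3683 ± 1996 CPM, a log2 fold change of 2.71 ± 0.45 (adjusted p = 0.0150). The variants dme-miR-965-3p_R+2 and ame-miR-2_R+2_1ss23CA both rose by 2.64 on the log2 scale (adjusted p = 0.0178), the first from 40.5 ± 19.8 to 253 ± 75.3 CPM and the other from 36.9 ± 13.0 to 230 ± 94.8 CPM. Members of the miR-2 family repress pro-apoptotic genes in Drosophila. The variant isc-miR-275_R+3, of a miRNA needed for blood digestion in mosquitoes, rose from 143 ± 39.7 to 628 ± 265 CPM (log2 fold change 2.14 ± 0.41, adjusted p = 0.0287). The variant tca-miR-14-3p_R+3 rose from 505 ± 156 to 2139 ± 1051 CPM (2.08 ± 0.43, adjusted p = 0.0392). This row passed in 7 of 14 alternatives that keep all libraries, where its adjusted p reached 0.0798, and in 1 of the 6 fits with a library left out, that without RBSDV-infected replicate 3. The variant tur-miR-184-3p_R+2 rose from 2297 ± 419 to 6321 ± 685 CPM (1.46 ± 0.20, adjusted p = 0.00603). Among candidates, PC-5p-33_137169 rose from 4857 ± 910 to 14364 ± 1905 CPM (1.56 ± 0.20) and PC-3p-70_56816 from 3291 ± 322 to 8667 ± 689 CPM (1.40 ± 0.18), each with an adjusted p of 0.00603. In all 9 rows the 3 infected libraries lay above the 3 virus-free ones.

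**Figure D1:**
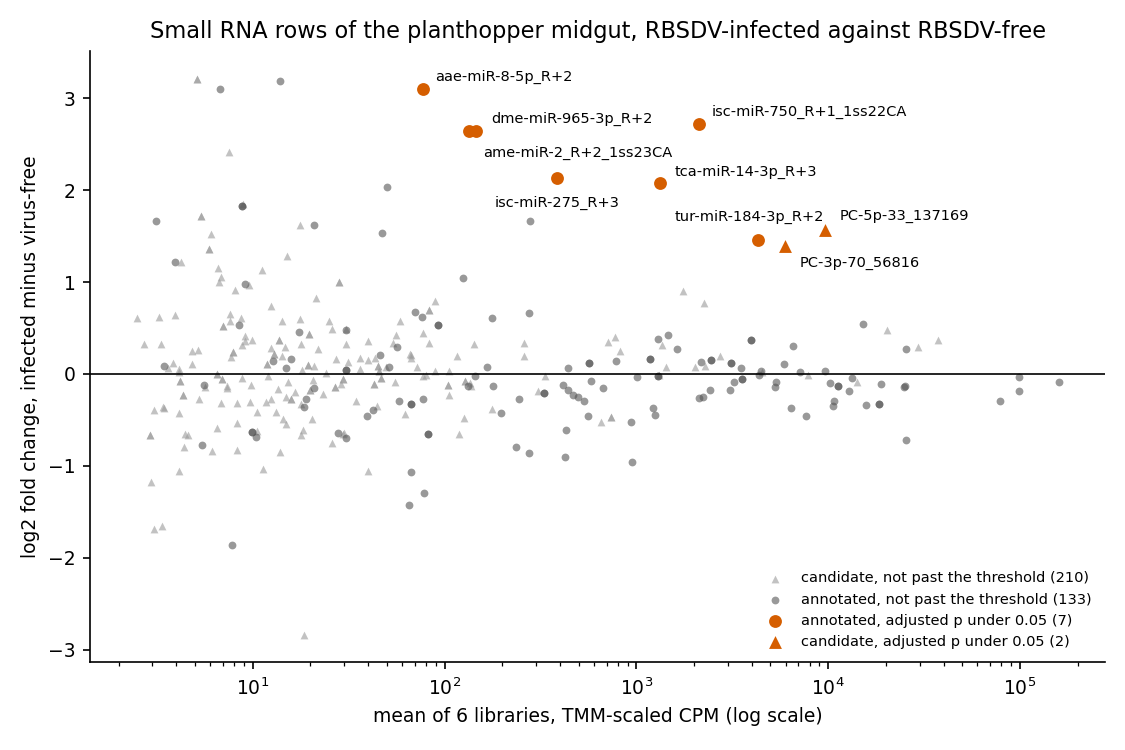
Log2 fold change (infected minus virus-free) against mean abundance (TMM-scaled CPM, log scale) for the 352 tested rows, with circles for annotated rows and triangles for predicted candidates. The 9 orange points are the rows with an adjusted p under 0.05, all between 1.40 and 3.10, while the most abundant rows lie near 0.

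**Figure D2:**
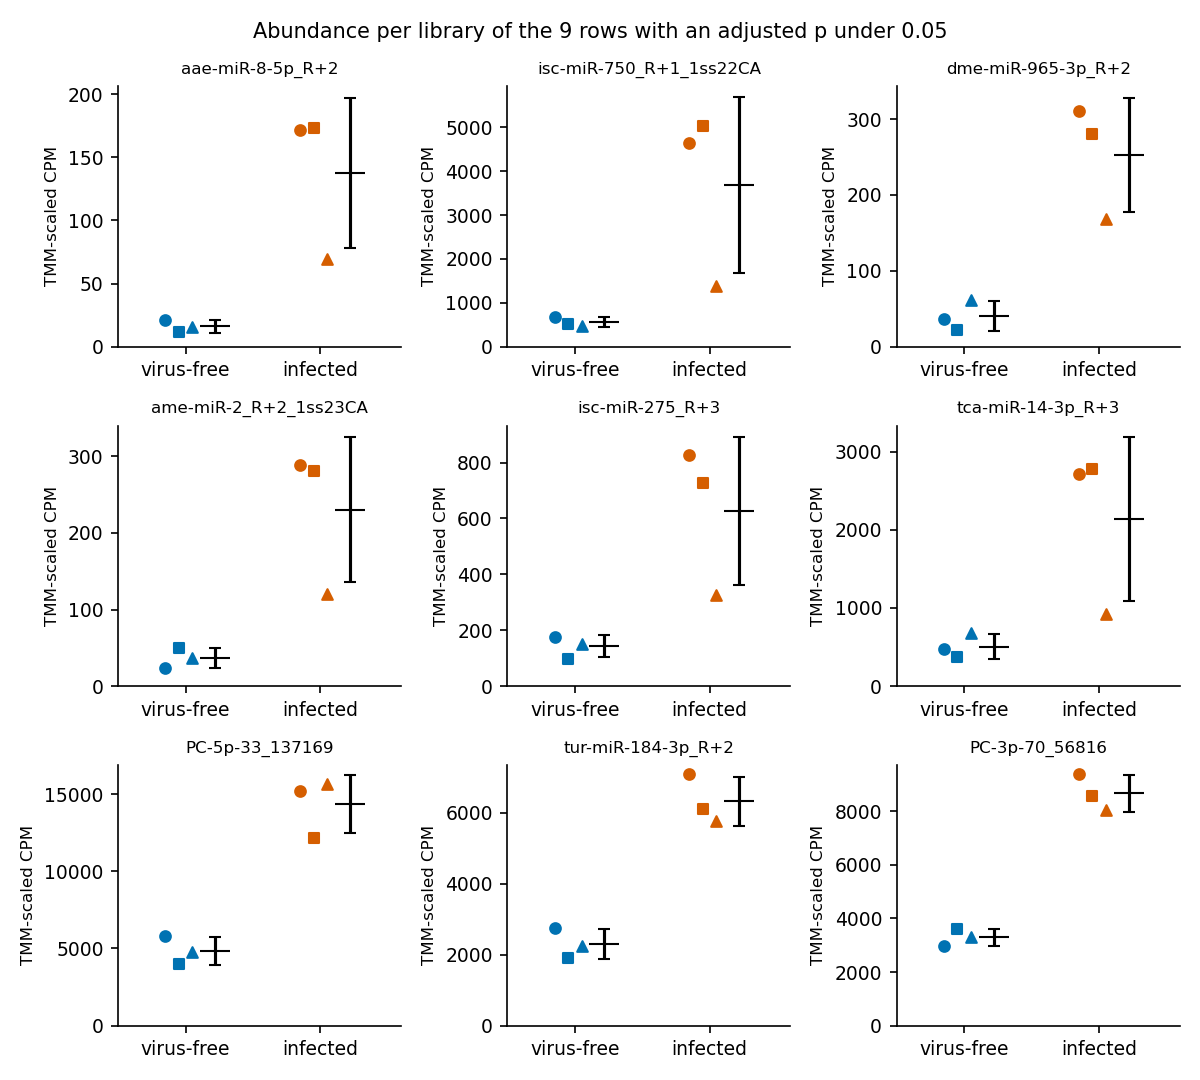
TMM-scaled CPM of the 9 rows per library, each panel with its own axis from 0, where circles, squares and triangles are replicates 1, 2 and 3 and the bar gives the mean ± SD (n = 3). Infected replicate 3 is the lowest infected library in 8 of the 9 panels, all but that of PC-5p-33_137169, and in every panel the groups do not overlap.

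Over all tested rows, 48 (13.6%) had no overlap between the groups, where chance gives 10% with 3 against 3 libraries. At an unadjusted p under 0.05 there were 25 higher and 4 lower rows, and DESeq2 called 12 higher and 1 lower. Infected replicates 1 and 2 carried the largest rises: isc-miR-750_R+1_1ss22CA stood at 4637 and 5024 CPM there and at 1389 CPM in infected replicate 3. The count of 9 fell to 4 without RBSDV-free replicate 1, to 2 without RBSDV-free replicate 2, to 0 without RBSDV-free replicate 3, to 2 without RBSDV-infected replicate 1 and to 2 without RBSDV-infected replicate 2, and rose to 14 without RBSDV-infected replicate 3, of which 2 were lower. The 2 candidates passed in 5 of these 6 fits. With annotated rows alone 5 rows passed, and with no filter 16.

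No row passed as lower in edgeR, and the 5 rows with the smallest p in that direction did not pass the threshold. They were ame-miR-1175_1ss17AT, of a miRNA clustered with the gut miRNA miR-1174 in mosquitoes, at 31678 ± 4667 CPM in virus-free and 19194 ± 6684 in infected libraries (log2 fold change −0.72 ± 0.25, adjusted p = 0.330), PC-3p-16404_226 (−2.84 ± 1.09), dvi-miR-10-5p_L+1_1ss23TA (−1.30 ± 0.52), PC-5p-12465_277 (−1.06 ± 0.44) and api-miR-996 (−0.79 ± 0.38). Without RBSDV-infected replicate 3 the miR-1175 row passed at −1.07 (edgeR adjusted p = 0.00812), as did dme-miR-34-5p_R-2 at −0.80 (adjusted p = 0.0460). With no filter it passed at −0.78, and PC-3p-16404_226 passed at −2.91. The latter stood at 74.1 CPM in RBSDV-free replicate 3 and at 12.9 and 10.7 CPM in the other virus-free libraries, and was at −1.39 without RBSDV-free replicate 3.

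The 7 annotated rows that rose were all longer variants, while the most abundant form of the same miRNA and arm did not pass the threshold. Each was 1 to 3 nt longer than the most abundant row of its miRNA and arm. The shares show the shift: isc-miR-750_R+1_1ss22CA (24 nt) amounted to 0.350% ± 0.0553 of isc-miR-750 (23 nt) in virus-free libraries and 2.42% ± 1.34 in infected ones (SD, n = 3). The row dme-miR-965-3p_R+2 went from 3.90% ± 2.03 to 35.0% ± 15.5 of dme-miR-965-3p, and tur-miR-184-3p_R+2 from 19.2% ± 2.31 to 72.6% ± 25.2 of dme-miR-184-3p_R+1. The row ame-miR-2_R+2_1ss23CA went from 0.309% ± 0.0858 to 2.19% ± 0.995 of dme-miR-2b-3p_L-2R+1_1ss19GT, aae-miR-8-5p_R+2 from 0.378% ± 0.122 to 3.10% ± 1.42 of lmi-miR-8-5p, and tca-miR-14-3p_R+3 from 0.482% ± 0.158 to 2.37% ± 1.26 of dme-miR-14-3p. The leading rows themselves had log2 fold changes from −0.53 to 0.54, with 0.336 as the smallest adjusted p.

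This contrast was tested after the data were seen. Among annotated names, 7 of 33 longer variants and 0 of 92 other names passed in edgeR, a count that restates the observation, so no p-value is given for it. The ratio of longer to leading row was higher in infected libraries for 9 of the 33 variants and lower for 0 (limma, adjusted p under 0.05). These 9 held 6 of the 7 rows above, since isc-miR-275_R+3 had a ratio change of 1.53 ± 0.54 (adjusted p = 0.0742) beside a log2 fold change of 0.54 ± 0.20 of its leading row dme-miR-275-3p. Of the 33 longer variants 25 had a log2 fold change above 0, with a median of 0.54 over all 33. Among those that passed in neither test were dme-miR-2a-3p_R+1 (24 nt), at a log2 fold change of 0.04 ± 0.16, and aae-miR-8-3p_R+2 (25 nt) at −0.23 ± 0.31, both chosen after their values were seen. Rows of 24 to 26 nt held 5.14%, 4.63% and 6.50% of counts in the virus-free libraries and 8.67%, 8.14% and 5.29% in the infected ones (exact permutation p = 0.2). With each library's trend on sequence length removed, 4 of the 7 rows passed. The rows ame-miR-2_R+2_1ss23CA, isc-miR-275_R+3 and tur-miR-184-3p_R+2 did not, at log2 fold changes of 1.86 ± 0.48, 1.32 ± 0.31 and 1.11 ± 0.24. The count of 9 ratios was 0 without RBSDV-free replicate 1 or RBSDV-infected replicate 1, 3 without RBSDV-infected replicate 2 and 14 without RBSDV-infected replicate 3, of which 1 was lower.

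**Figure D3:**
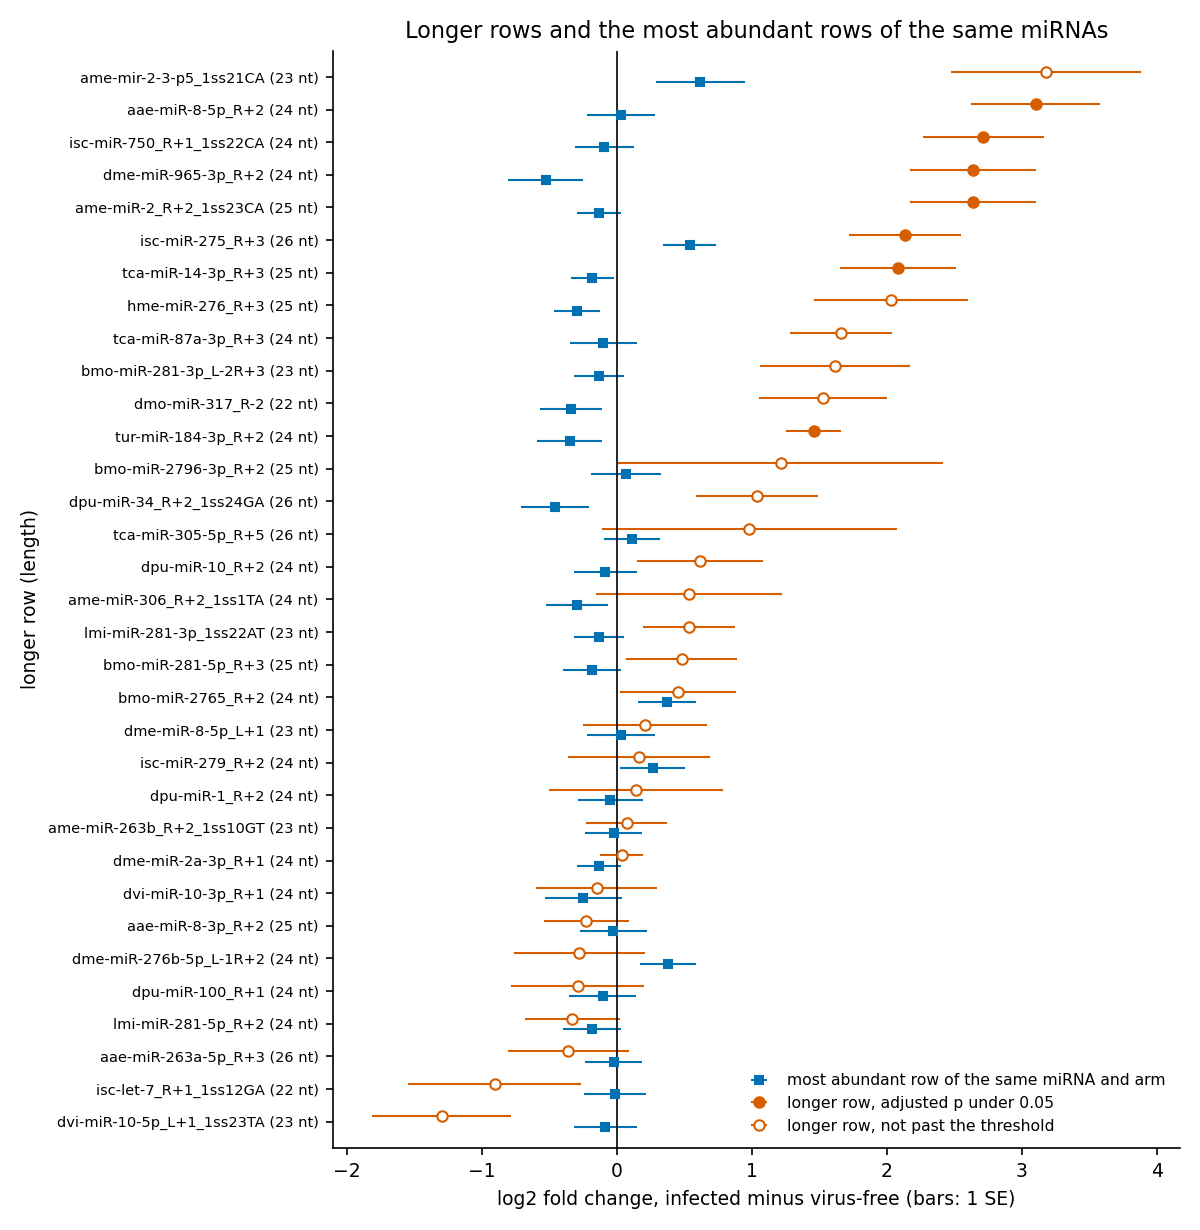
Log2 fold change (infected minus virus-free, ± 1 SE) of the 33 longer variants (orange circles, filled where the adjusted p is under 0.05) and of the most abundant row with the same miRNA number and arm (blue squares). The 7 filled circles lie between 1.46 and 3.10, while the squares beside them lie between −0.53 and 0.54.

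When the annotated variants were summed per miRNA number and arm, 0 of 75 miRNAs passed in edgeR and 0 in DESeq2, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.580. The miRNA closest to the threshold was miR-275 3p, at 14475 ± 3010 CPM in virus-free and 22549 ± 2827 CPM in infected libraries (log2 fold change 0.64 ± 0.20). The next was miR-1175 3p, at 36448 ± 3885 and 23182 ± 7150 CPM (−0.65 ± 0.23).

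The lists fixed before the data were examined asked whether related miRNAs moved together. Of 17 lists, 14 had at least 3 tested rows, and 0 passed in camera after adjustment, with the preset or the estimated correlation, or in fry for a common direction. At an unadjusted p under 0.05 camera gave 3 lists: the miR-275 and miR-305 cluster, the let-7 complex and the midgut markers. In fry's test for change in either direction 6 lists passed, which were the miR-2 family with miR-71, the miR-34 cluster, the miR-275 and miR-305 cluster, the growth and metabolism miRNAs, the Toll or Imd regulators and the midgut markers. All of these but the miR-34 cluster held at least 1 row that had passed in edgeR, and some share such rows. Except for that of the miR-34 cluster, the calls are therefore not separate from the risen variants above.

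The miR-275 and miR-305 cluster, 2 miRNAs from the same locus with gut and metabolic roles in insects, came closest, with a median log2 fold change of 0.76 over 4 rows and a camera adjusted p of 0.0543 (adjusted p = 0.587 with an estimated correlation). Its adjusted p was 0.0440 with library totals alone and 0.0470 with the replicate number as a block, and these calls were lost with an estimated correlation (adjusted p = 0.549 and adjusted p = 0.866). Of its 4 rows isc-miR-275_R+3 passed alone, 2 passed when adjusted over the list alone, and dme-miR-275-3p and dme-miR-305-5p_R+1 had log2 fold changes of 0.54 ± 0.20 and 0.11 ± 0.21. The remaining row, tca-miR-305-5p_R+5, named outside the rule, was at 0.98 ± 1.09. It amounted to 0.112% ± 0.111 of dme-miR-305-5p_R+1 in virus-free libraries, with 0 in RBSDV-free replicate 2. The median of the list lies between this rare row and dme-miR-275-3p. The 16 midgut marker rows (miR-281, miR-275, miR-8 and miR-1174) had a median of 0.12, with 2 rows past the threshold and 2 when adjusted over the list alone. Without RBSDV-free replicate 2 this median turned to −0.09, and without RBSDV-free replicate 3 it was 0.26. Their most abundant members, dme-miR-8-3p and dme-miR-281-3p_R-1_2ss10AG22GA, were at −0.03 ± 0.25 and −0.13 ± 0.19, and the first of these turned to 0.02 with library totals alone.

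The 19 growth and metabolism rows (bantam, miR-8, miR-14, miR-278, miR-184 and miR-276) held 3 of the risen variants, or 4 when adjusted over the list alone. Their median log2 fold change was −0.17 and their mean 0.28, so the median and the mean, with the direction of the test, differed in sign. The abundant forms dme-miR-14-3p and dme-miR-276b-3p_2ss10AC21CT stood at −0.18 ± 0.16 and −0.29 ± 0.17. The 13 rows of the miR-2 family with miR-71, which include 5p and 3p products of miR-2 and miR-71 and 3p products of miR-13, had a median of 0.12, with 1 row past the threshold and 2 when adjusted over the list alone. This median turned to −0.04 without RBSDV-free replicate 1 and to −0.0017 without RBSDV-infected replicate 3. The abundant bmo-miR-13a-3p_R+1_2ss20TA21GA was at −0.14 ± 0.18, and dme-miR-2b-3p_L-2R+1_1ss19GT and dme-miR-2a-3p_L-2R+1, with identical counts, at −0.13 ± 0.16. The 13 rows named for Toll or Imd signalling in Drosophila (let-7, miR-8, miR-317, miR-34 and others) had 1 row past the threshold, aae-miR-8-5p_R+2, and 1 adjusted over the list alone. Their median was −0.03 and their mean 0.24, again of opposite sign, and the median turned to 0.0099 with library totals alone.

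The 7 rows of the let-7 complex, a cluster induced around metamorphosis, had a median log2 fold change of −0.26 (camera adjusted p = 0.216, and adjusted p = 0.877 with an estimated correlation). Their abundant members were bmo-miR-100 at −0.11 ± 0.25, dme-let-7-5p at −0.02 ± 0.23 and dme-miR-125-5p_1ss16CT at −0.26 ± 0.27. In the miR-34 cluster dme-miR-317-3p_R-3_1ss21CT, dme-miR-34-5p_R-2 and dme-miR-277-3p stood at −0.34 ± 0.23, −0.46 ± 0.25 and 0.02 ± 0.19. The median of its 5 rows was 0.02, which turned to −0.06 with DESeq2-type size factors and to −0.02 with identical rows kept once. The 8 rows of the miR-9 family had a median of −0.22, with the test in the same direction, and a mean of 0.0067 of opposite sign. They included dme-miR-9a-5p at −0.33 ± 0.28, dme-miR-9a-3p_L+1_1ss11CG at 0.12 ± 0.27 and dme-miR-79-3p_L+1R-1_1ss10GT at −0.61 ± 0.35.

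In the remaining families 0 rows passed, over all rows or over the list alone. The miR-279 family had a median of −0.04 over 5 rows, with bmo-miR-279c-3p_1ss12AT at 0.27 ± 0.24, dme-miR-279-3p_2ss20TC21AC at −0.04 ± 0.19 and bmo-mir-279a-p3_1ss19TA at −0.37 ± 0.36. The Hox cluster miRNAs had a median of −0.15 over 9 rows, with bmo-miR-10-5p_L+1, bmo-miR-993a-3p and bmo-miR-993a-5p_L-2R+1_1ss23TA at −0.08, −0.15 and −0.29. The miR-92 family had 3 rows but 2 distinct names, since dme-miR-92a-3p_1ss1CT stands in the table as 2 tested rows with the same values, so its median of 0.17 is that of this row and it was not tested with identical rows kept once. The other member, tca-miR-92b-3p_L+1R+1, was at 0.27. The miR-263 and miR-183 family had a median of −0.02 over 4 rows (0.01 with library totals alone), with dme-miR-263a-5p_R-2, ame-miR-263b_R+2_1ss10GT and aae-miR-263a-5p_R+3 at −0.02, 0.07 and −0.36. Of the cluster of miR-12, miR-283 and miR-304 1 of 3 rows was tested, dpu-miR-12, at 1.33 ± 2.30 CPM in virus-free and 12.2 ± 9.34 in infected libraries (adjusted p = 0.617).

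The shares of marker miRNAs of other tissues differed between the groups by less than the spread between libraries. Muscle marker rows (miR-1, miR-133 and miR-206) held 0.965% ± 0.0789 of counts in virus-free and 0.916% ± 0.177 in infected libraries, with dme-miR-1-3p, dme-miR-133-3p and bmo-miR-1a-5p_R+1 at log2 fold changes of −0.05, −0.25 and 0.04. Neuron marker rows (miR-124, miR-137, miR-210 and miR-7) held 0.943% ± 0.224 and 0.889% ± 0.132, with tca-miR-137-3p_L-1R+1, dme-miR-7-5p_R+1 and dme-miR-124-3p_R-2 at −0.09, 0.13 and −0.96. The last of these was at −0.25 without RBSDV-free replicate 2, where it stood at 2301 CPM beside 610 and 869 CPM in the other virus-free libraries. As lists, muscle had a median of −0.0028 over 6 rows, and neuron a median of 0.00019 beside a mean of −0.04 and a test direction of Down over 8 rows. The medians changed sign with another scaling, muscle to 0.02 with library totals alone and neuron to −0.10 with DESeq2-type size factors. Midgut marker rows held 15.5% ± 1.40 and 16.03% ± 2.55. Plant miRNAs and vertebrate-type miRNAs had 0 rows in the table.

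Predicted candidates took a larger share of counts in infected midguts, 17.7% ± 1.01 against 13.4% ± 1.19 (SD, n = 3), and the groups did not overlap. The exact permutation p was 0.1, the smallest this design allows, and 0.9 after adjustment over 9 measures of composition. Of the difference of 4.30 percentage points, PC-5p-33_137169 and PC-3p-70_56816 supplied 1.53, and PC-3p-12_317818 and PC-3p-16_259636, whose own changes did not pass the threshold, supplied 1.03 and 0.663. The number of rows detected was 528 ± 38.7 in virus-free and 527 ± 69.2 in infected libraries, and the 10 most abundant rows held 61.3% ± 1.98 and 59.1% ± 0.663 of counts (exact permutation p = 1 and 0.3).

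The arm ratio asked whether the 5p and 3p products of a precursor shifted against each other. Names paired both arms for 19 precursors, 15 were tested, and 1 passed (limma, adjusted p under 0.05), with 4 at an unadjusted p under 0.05. The log2 5p/3p ratio of aae-miR-8 rose by 3.19 ± 0.39 (SE, adjusted p = 0.00198), from −4.95 ± 0.53 to −1.75 ± 0.56 (SD, n = 3). This pair consists of the longer variants aae-miR-8-5p_R+2 and aae-miR-8-3p_R+2, so it is the rise of the first of these seen again. The abundant miR-8 rows are named after different species and were not paired with each other. The count was 5 without RBSDV-infected replicate 3, with 2 ratios higher and 3 lower.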

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

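The authors' scaling, the summing of rows of a name or of a miRNA, the length correction and every setting of the longer-to-leading ratio were chosen after the data were seen. Depth was 1903738 to 3277015 counts per library. At 8-fold 94.3% of simulated changes were recovered, at 2-fold 24.1%, in a simulation with far more changed rows than were called in the data and 1 common dispersion for all rows. Of the 9 rows, 8 or 9 passed with the other scalings, the authors' scaling, rows of a name summed, the 10 CPM filter, limma-voom, no robust dispersion, identical rows kept once and the 3 most abundant rows left out, all 9 with DESeq2 (13 rows passed) and upper quartile (11), and 6 with the length trend removed. The row lost with library totals, the 10 CPM filter, limma-voom, identical rows kept once and the 3 most abundant rows left out was tca-miR-14-3p_R+3. The count was 16 with no filter (904 rows tested), 5 with annotated rows only, 0 with annotated rows summed per miRNA number and arm, and 0 to 14 with a library left out. Fewer libraries enter those last fits, and for the others the cause was not tested. List calls were 1 with library totals only and 0 in the other scalings, with identical rows kept once, with the estimated correlation or with a library left out. With a library left out the medians of 8 of the 14 lists changed sign in at least 1 fit: the miR-2, miR-34, miR-263 and miR-279 lists, the Toll or Imd regulators and the midgut, muscle and neuron markers. Arm ratio calls ran from 1 to 5, and the longer-to-leading calls from 0 to 14, with a library left out, and were 10 with a pseudocount of 1. Composition differences moved by less than the spread between libraries.

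The labels do not say that the replicate numbers pair the libraries, so they were treated as unpaired. The deviations of same-numbered libraries from their group means correlated at 0.256, 0.0886 and 0.0380. In these data 5 of the 6 libraries correlated best with their own number, and RBSDV-free replicate 3 with another (0.0429). These correlations are low, and the 6 matches are not independent because the deviations share group means, so they do not show a pairing. With the replicate block 8 rows (all of the 9 but tca-miR-14-3p_R+3), 1 list, 3 arm ratios (1 higher and 2 lower) and 7 longer-to-leading ratios passed.

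Among the named rows 11 calls were lost and 2 gained over the settings that keep all libraries, and 35 lost and 2 gained over those that leave 1 out. The rows that changed sign were all past no threshold, and the cause was not tested. With DESeq2-type factors ame-miR-263b_R+2_1ss10GT was at −0.0068, bmo-miR-1a-5p_R+1 at −0.032 and dme-miR-277-3p at −0.063. With the DESeq2 Wald test these were at −0.013, −0.037 and −0.069. With no filter the last 2 were at −0.012 and −0.040, and with the authors' scaling at −0.019 and −0.049. The row dme-miR-277-3p was at −0.025 with the 10 CPM filter and −0.019 with identical rows kept once. With library totals only dme-let-7-5p was at 0.0099, dme-miR-263a-5p_R-2 at 0.012 and dme-miR-8-3p at 0.025, and the last at 0.0092 with annotated rows only. With the length trend removed ame-miR-263b_R+2_1ss10GT was at −0.11, dme-let-7-5p at 0.12, dme-miR-277-3p at −0.13, dme-miR-305-5p_R+1 at −0.31, dme-miR-7-5p_R+1 at −0.27, dme-miR-9a-3p_L+1_1ss11CG at −0.041 and PC-3p-16_259636 at −0.078. With a library left out the ranges that crossed 0 were −0.061 to 0.12 (ame-miR-263b_R+2_1ss10GT), −0.31 to 0.042 (bmo-miR-10-5p_L+1), −0.12 to 0.089 (bmo-miR-1a-5p_R+1), −0.072 to 0.35 (bmo-miR-279c-3p_1ss12AT), −0.29 to 0.087 (dme-let-7-5p), −0.31 to 0.082 (dme-miR-1-3p), −0.16 to 0.048 (dme-miR-263a-5p_R-2), −0.14 to 0.098 (dme-miR-277-3p), −0.18 to 0.026 (dme-miR-279-3p_2ss20TC21AC), −0.052 to 0.21 (dme-miR-305-5p_R+1), −0.068 to 0.28 (dme-miR-7-5p_R+1), −0.21 to 0.16 (dme-miR-8-3p), −0.096 to 0.28 (dme-miR-9a-3p_L+1_1ss11CG), −0.29 to 0.054 (isc-miR-750) and −0.26 to 0.0046 (tca-miR-137-3p_L-1R+1).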

Other observations

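The tests of explanations below, other than the counts over splits of the libraries, were chosen after the results were seen, as were the ratios of longer to leading rows. Some longer variants gained on their leading row without passing as rows themselves. The variant dmo-miR-317_R-2 went from 0.136% ± 0.0620 to 0.503% ± 0.0250 of its leading row (SD, n = 3), a log2 ratio change of 2.01 ± 0.47 (limma, adjusted p = 0.0185). The 5p variant ame-mir-2-3-p5_1ss21CA went from 4.61% ± 1.21 to 25.9% ± 14.7 (2.24 ± 0.55, adjusted p = 0.0225) and tca-miR-87a-3p_R+3 from 1.33% ± 0.277 to 4.48% ± 2.17 (1.63 ± 0.49, adjusted p = 0.0471). The miR-2 row stood at only 2.72 ± 0.54 CPM in virus-free libraries, so its share there rests on few reads. Its leading row, bmo-miR-2a-2-5p_1ss18GA, carries the name of another miR-2 entry, so it may not be a shorter form of the same sequence. The largest change in the other direction was that of dvi-miR-10-5p_L+1_1ss23TA, at −1.16 ± 0.52, which did not pass (adjusted p = 0.144). These rows were chosen after their values were seen.

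Median changes over all tested names also differed by sequence length, which was not tested as a trend. The median log2 fold change was −0.53 for 6 names of 18 nt, −0.58 for 10 of 19 nt, −0.25 for 10 of 20 nt and −0.34 for 17 of 21 nt. It was −0.04 for 111 names of 22 nt, 0.08 for 93 of 23 nt and 0.13 for 35 of 24 nt. At 25 nt it was 0.48 for 13 names and at 26 nt 0.41 for 14 names, so it did not rise at every step. The fitted trend of a library's log2 deviations per nucleotide was −0.07, −0.27 and 0.08 in the virus-free libraries and 0.14, 0.26 and −0.13 in the infected ones, so infected replicate 3 did not share the sign of the other two.

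A first pattern is that longer variants of 7 miRNAs rose while the most abundant rows of the same miRNAs did not pass the test. More of the whole miRNA is argued against for 6 of the miRNAs, whose leading rows had a median log2 fold change of −0.16 beside 2.64 for the longer rows, but stays open for miR-275, whose leading row was at 0.54 ± 0.20 and whose ratio change of 1.53 ± 0.54 did not pass (limma, adjusted p = 0.0742). A trimming or adapter remainder that raised every longer row by the same factor, as large as those past the threshold, is argued against. In 15 of the 33 longer rows the 95% interval of the ratio change lay wholly below the smallest of those 9 changes, 1.63. That bar comes from changes picked for passing. The 15 also include pairs that a 3′ remainder need not raise, such as the paralog ame-miR-263b_R+2_1ss10GT and dme-miR-8-5p_L+1, read as longer at the left. Pairs that share a reference name ran from −0.63 ± 0.44 (dme-miR-276b-5p_L-1R+2) to 3.22 ± 0.61 (dme-miR-965-3p_R+2). Of the 33, 25 had a log2 fold change above 0. A smaller common factor, or a remainder that adds a like share of the leading row's reads, was not tested. The row dme-miR-2a-3p_R+1, at 81.0% of its leading row in virus-free libraries, could hardly show such a gain in its ratio. A straight-line effect of insert length is argued against as the whole cause for 4 of the 7 rows, which passed with the length trend removed. Of these, aae-miR-8-5p_R+2 went from 3.10 ± 0.48 to 2.68 ± 0.38 and isc-miR-750_R+1_1ss22CA from 2.71 ± 0.45 to 2.21 ± 0.37. The other rows were dme-miR-965-3p_R+2, from 2.64 ± 0.47 to 2.32 ± 0.33, and tca-miR-14-3p_R+3, from 2.08 ± 0.43 to 1.45 ± 0.25. A length effect that steepens among the longest rows would remain after a straight line is removed, and was not tested. Open stay a library batch, which is not labelled, and a change in how 3′ ends are trimmed or extended in infected midguts, a hypothesis that needs the sequences. Also open are a remainder in part of the longer rows or in proportion to the leading row, and an effect of insert length other than a straight line. For the other 3 rows a straight-line effect of insert length stays open too. With the trend removed their folds were lower, neither past the threshold nor within 1 SE of 0. They went from 2.64 ± 0.47 to 1.86 ± 0.48 (ame-miR-2_R+2_1ss23CA), 2.14 ± 0.41 to 1.32 ± 0.31 (isc-miR-275_R+3) and 1.46 ± 0.20 to 1.11 ± 0.24 (tur-miR-184-3p_R+2). The first of these stayed larger than tca-miR-14-3p_R+3, so the parting of the 7 rows rests on the threshold and not on size.

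A second pattern is that infected replicate 3 lay below infected replicates 1 and 2 in 8 of the 9 rows that rose. Virus-free material mixed into infected replicate 3 would place every such row at the same fraction of the way from the virus-free mean to the mean of infected replicates 1 and 2. This holds only if the infected part of replicate 3 was like infected replicates 1 and 2. The fractions ran from 0.188 for tca-miR-14-3p_R+3 to 1.22 for PC-5p-33_137169, a difference of 1.04, and PC-3p-70_56816 and tur-miR-184-3p_R+2 stood at 0.835 and 0.806. Such mixing as the whole cause is argued against only under that condition. The spread of a further infected library and of the virus-free mean was not counted, and could part the fractions too. A difference in the stage or level of infection between the libraries may exist, and was not tested because the labels give neither. A difference in insert length stays open as well and was not tested for this pattern. Rows of 24 to 26 nt held 5.29% of counts in infected replicate 3, beside 8.67% and 8.14% in infected replicates 1 and 2. The fractions of the candidates above belong to rows of 23 nt. Those of 24 nt ran from 0.194 to 0.806, and those of 25 and 26 nt from 0.188 to 0.339.

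The 6 libraries can be parted into 3 and 3 in 10 ways, so no share under 0.05 can be reached. The real split gave 9 rows past the threshold, 1 arm ratio and 9 longer-to-leading ratios, and the highest of the other splits gave 0 for each of the 3 counts. The real split alone (1 of 10) reached its value in each. The smallest camera p of a list was 0.00388 in the real split, and 4 of the 10 splits, the real one included, gave a p as small, the smallest other being 7.73e-05.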
